A study of Mus musculus with 12 samples.

How the data were processed

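Gene expression was measured in 12 mouse skin samples with 1 Affymetrix array each, 3 at each of 0 hours, 2 hours, 3 days and 14 days after thermal injury, from total RNA. Groups and replicate numbers were taken from the sample labels. The deposited values are linear signal intensity per probe set, 1 value per array and without detection calls. The authors may have scaled each array by a single factor to a common trimmed mean, but the values do not settle this. The 2% trimmed mean was 818.2 for 0 hours replicate 3, against 909.6 and 904.1 for 0 hours replicates 1 and 2. The scaling target, the software and the rule by which probe sets were kept are not given in the sources used here.

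The table held 7275 probe sets, of which 27 were control probe sets left out of the tests. The annotation table held 6814 of them. Exactly 1 gene symbol was named by 6551 probe sets (5599 genes), several by 251 and none by 446. The last 2 kinds were tested apart from the genes.

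The 2% trimmed means of the arrays deviated from their mean by at most 8.56%, under the limit of 10%, so the deposited intensity was used without further scaling. Values under the pooled 25th percentile (225.375) were set to it as a floor and log2-transformed. Probe sets above the pooled median (475.55) on at least 3 arrays were kept (4235), and for each gene the one with the highest mean was used, which left 3477 genes. A fold against a group with any array at the floor is a lower bound.

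All 12 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 1 coefficient per time point, 8 residual and 6.64 prior degrees of freedom. The contrasts were 2 hours, 3 days and 14 days against 0 hours, 3 days against 2 hours, and 14 days against 3 days. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. An exact test of 3 against 3 arrays cannot give a p under 0.1. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

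Gene lists (35, with 1021 entries, of which 661 had a probe set) were written from general knowledge before the data were examined, as were the comparisons, tests, floor, filter and the rule for naming genes. The 28 lists with at least 5 tested genes were tested with limma camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over lists. Single genes were also adjusted over the list alone. Named genes are the 8 largest rises and the 8 largest falls among called genes without overlap between the groups, and up to 4 members with the smallest p of each list described. The 2 comparisons between later time points name the 4 largest rises and falls. Other named genes are stated to have been chosen after their values were seen.

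Alternatives were quantile normalization, median scaling, floors at the 10th (113.69) and 40th (360.7) percentile, no filter, a filter at the 75th percentile, the probe set with the highest variance, trended and robust variance, array weights, a replicate block, a log2 change of at least 1, only the 2 time points compared, and each array left out in turn. Covariates for the Gapdh 3′ to 5′ ratio and the muscle marker mean, and a test without muscle and oxidative phosphorylation genes, were chosen after seeing the data. Equal replicate numbers did not pair the arrays: of 18 same-numbered pairs 2 had a correlation over 0.1 (median −0.066).

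The procedure was tested on simulated data made from these arrays. Shifts of 1 on the log2 scale were recovered for 66.7%, 78.1% and 59.1% of genes at 2 hours, 3 days and 14 days, and shifts of 2 for 94.6%, 98.0% and 92.8%. False calls made up 3.18%, 6.52% and 3.33% of the calls. With 1 list shifted by 0.7, camera at its preset correlation also called 1, 1 and 0 other lists at 2 hours, 3 days and 14 days. Each comparison had a single run, with noise drawn independently for each probe set. The simulated arrays held no change of RNA quality or muscle signal with time. These shares may therefore not carry over to the real arrays.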

Results

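RNA from mouse skin was hybridised to Affymetrix oligonucleotide arrays, with 1 array per sample and 12 arrays in all. Skin had been excised at 0 hours, 2 hours, 3 days and 14 days after a thermal injury, and each time point held 3 replicates. The labels do not say whether the 0 hours skin was burnt, nor whether the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Array medians lay between 448.4 and 496.4 signal units, and 3477 genes were bright enough to be tested. The number of arrays limits the precision of each value. Errors after ± are standard errors of the limma fit with 3 arrays per time point unless SD is named.

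Arrays of the same time point had Spearman correlations of 0.876 to 0.960, against 0.803 to 0.940 between time points. The array of 0 hours replicate 3 stood furthest apart, with a mean correlation of 0.851 with the other arrays. The Gapdh control probe sets, whose signal ratio between the 3′ and 5′ ends of the transcript is a measure of RNA quality, differed between time points. The log2 ratio was 1.99 ± 0.29 (SD, n = 3) at 0 hours, 1.54 ± 0.46 at 2 hours, 0.52 ± 0.50 at 3 days and 0.21 ± 0.08 at 14 days. The same ratio of the beta-actin control probe sets ran differently, at 0.01 ± 0.21 (SD, n = 3), 0.74 ± 0.54, 0.23 ± 0.11 and 0.35 ± 0.07, while the beta-actin ratio of the 3′ end to the middle was 2.77 ± 0.35, 1.99 ± 0.57, 1.19 ± 1.05 and 1.07 ± 0.23. The mean log2 signal of skeletal muscle markers was 12.60 ± 0.38 (SD, n = 3) at 0 hours, 12.13 ± 0.09 at 2 hours, 11.64 ± 0.51 at 3 days and 11.77 ± 0.24 at 14 days. The Gapdh ratio and the muscle signal were lower at 3 days and 14 days than at 0 hours, and from 3 to 14 days neither moved beyond its SD. The limma F-test over the 4 time points called 736 genes at a Benjamini-Hochberg adjusted p under 0.05.

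**Figure D1:**
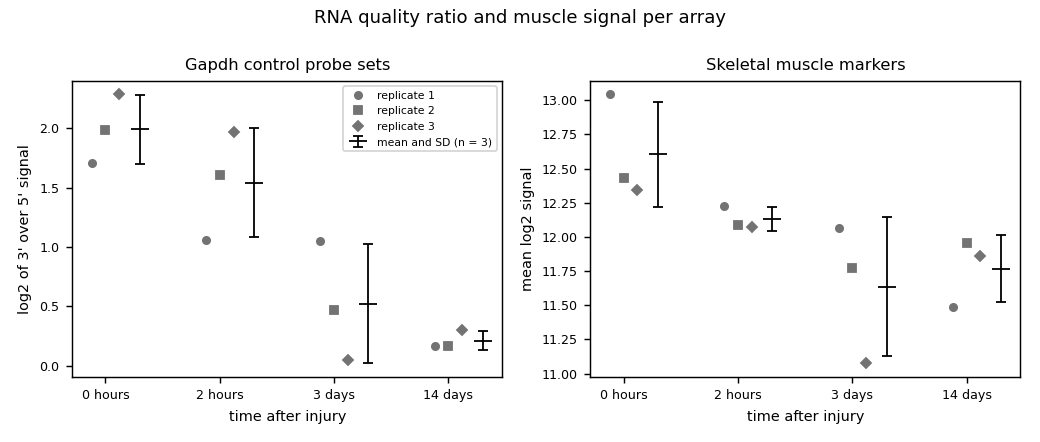
Log2 ratio of the 3′ over the 5′ Gapdh control probe sets (left) and mean log2 signal of skeletal muscle markers (right) for each of the 12 arrays, by time after injury; symbols mark replicates, and bars the mean and SD of 3 arrays. The ratio was 1.99 on average at 0 hours and 0.21 at 14 days, and the muscle mean 12.60 and 11.77.

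The comparison of 2 hours with 0 hours asks which transcripts changed early after the injury. Heat shock genes had the largest rises. Hspa1a, an inducible Hsp70 chaperone, rose 17.0-fold (log2 change 4.09 ± 0.26, limma adjusted p = 4.9e-07), and its near-identical paralog Hspa1b rose 10.1-fold (3.34 ± 0.31), although cross-hybridisation leaves the share of each uncertain. The chaperones Hsp90aa1 and Hsph1 rose 7.49-fold and 5.16-fold. Of 20 heat shock and chaperone genes tested, 9 rose, none fell and 11 were not called; adjusted over the list alone, 13 rose and 1 fell. The median log2 change of the list was 0.76, and its limma camera call was lost with an estimated correlation (adjusted p = 0.49 with an estimated correlation).

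The metallothioneins Mt1 and Mt2, metal-binding stress proteins, rose 8.74-fold (3.13 ± 0.23) and 5.09-fold (2.35 ± 0.20) at 2 hours, and Hmox1, which degrades haem, rose by 1.47 ± 0.22. These were the 3 called genes of 18 in the oxidative stress list, or 4 adjusted over the list alone, with a median of 0.16 (adjusted p = 0.60 with an estimated correlation). Among the remaining largest rises were Wdr92 (2.37 ± 0.34) and Zbtb16 (2.33 ± 0.42), a zinc-finger transcription factor. Of 25 immediate-early genes, 8 rose and none fell, or 11 and none adjusted over the list alone, with a median of 0.67 (adjusted p = 0.60 with an estimated correlation). They included the stress transcription factor Atf3 (1.92 ± 0.32), the matrix-associated growth regulator Ccn2 (1.74 ± 0.37), Klf10 (0.95 ± 0.21) and Klf6 (1.03 ± 0.25). Without 2 hours replicate 3 the calls of Ccn2, Klf10 and Klf6 were lost, with limma adjusted p of 0.073, 0.092 and 0.094.

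Early inflammatory transcripts were higher at 2 hours in part. Of 11 chemokines, Ccl7 (1.91 ± 0.42), Ccl9 (1.24 ± 0.30) and Ccl2 (2.25 ± 0.60) rose, 8 were not called, and the median was 0.25, with 3 called adjusted over the list alone (adjusted p = 0.60 with an estimated correlation). All 3 calls were lost without 2 hours replicate 1, with limma adjusted p of 0.070, 0.083 and 0.10. Of 13 inflammatory cytokines and receptors only Osmr, the oncostatin M receptor, rose (1.49 ± 0.25), or 3 adjusted over the list alone, with a median of 0.50 (adjusted p = 0.60 with an estimated correlation). In the wound keratinocyte list, Sprr1a (1.74 ± 0.32), Krt6a (1.67 ± 0.36) and S100a10 (0.85 ± 0.21) rose of 14 tested, or 3 up and 1 down adjusted over the list alone, and the list itself was not called (limma camera adjusted p = 0.21). The calls of Krt6a and S100a10 were lost without 2 hours replicate 3, with limma adjusted p of 0.066 and 0.15. Krt6a is nearly identical to Krt6b, so its identity is uncertain. Of 12 basal keratinocyte markers 1, Col17a1, rose (1.16 ± 0.24), or 3 adjusted over the list alone, and its call was lost without 2 hours replicate 3 (limma adjusted p = 0.069); the list median was 0.37 (adjusted p = 0.60 with an estimated correlation). Of 17 ribosomal protein genes 0 were called by limma, and 0 adjusted over the list alone, with 4 up at an unadjusted p under 0.05, although camera called the list up with a median of 0.26 (adjusted p = 0.60 with an estimated correlation).

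Among the falls at 2 hours were muscle and matrix genes. Tnnt1 and Tnni1, troponins of slow muscle fibres, changed by −2.35 ± 0.63 and −1.98 ± 0.52 on the log2 scale, and with Cacng1 (fell by 0.68 ± 0.19) they were the 3 called of 34 muscle markers, or 4 adjusted over the list alone. Without 0 hours replicate 1 the changes of Tnnt1 and Tnni1 were −1.30 and −1.22, and that of Tnnt1 was −3.14 without 0 hours replicate 3. The muscle list had a median of −0.35 (adjusted p = 0.60 with an estimated correlation). Without 2 hours replicate 3 the 3 calls were lost, with limma adjusted p of 0.16, 0.089 and 0.17. Of 36 collagens and matrix proteins 5 fell and none rose, or 11 fell and 3 rose adjusted over the list alone, with a median of −0.12 (adjusted p = 0.60 with an estimated correlation). These were Col1a2 (fell by 1.61 ± 0.19), Sparc (fell by 1.07 ± 0.19), Col1a1 (fell by 0.92 ± 0.18), Mfap2 (fell by 0.91 ± 0.22) and Col3a1 (fell by 0.87 ± 0.23). A weaker probe set of Col1a2 gave −0.28 and a weaker probe set of Col1a1 gave −1.73. Without 2 hours replicate 3 the calls of Mfap2 and Col3a1 were lost, with limma adjusted p of 0.088 and 0.11.

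The proteases Ctsk (fell by 1.27 ± 0.19) and Mmp3 (fell by 1.35 ± 0.29) also fell at 2 hours, while Serpinb2 (1.17 ± 0.29) and Adam8 (1.16 ± 0.30) rose, among 19 matrix proteases and inhibitors, or 3 up and 4 down adjusted over the list alone. The list was not called (limma camera adjusted p = 0.37), and without 2 hours replicate 2 the calls of Mmp3, Serpinb2 and Adam8 were lost, with limma adjusted p of 0.062, 0.088 and 0.062. Among 19 genes of fatty acid and sterol synthesis, Scd2 (fell by 1.37 ± 0.19) and Acly (fell by 1.10 ± 0.21) fell, or 4 adjusted over the list alone, with a median of −0.38 (adjusted p = 0.49 with an estimated correlation). The hair follicle keratin Krt71 was at the floor on all 3 arrays at 2 hours and fell at least 4.05-fold (limma adjusted p = 0.025), with a log2 change of −2.79 without 0 hours replicate 1. S100a3, a hair cuticle protein, fell by 1.52 ± 0.41, although its other probe set gave −0.01. They were the 2 called of 15 hair follicle markers, or 3 adjusted over the list alone, with a median of −0.75 (adjusted p = 0.60 with an estimated correlation). That median was −0.27 without 0 hours replicate 2. Without 0 hours replicate 3 the calls of Krt71 and S100a3 were lost, with limma adjusted p of 0.10 and 0.12. Other large falls were those of Hnrnpl (fell by 2.19 ± 0.33), Kdelr3 (fell by 1.60 ± 0.30) and Pcyt2 (fell by 1.55 ± 0.20). At 2 hours the changes of Ccl7, Ccl2, Adam8, Tnnt1, Tnni1, Hnrnpl and S100a3 are lower bounds in size, because 1 or 2 of the 3 arrays of the lower group were at the floor.

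Fibroblast markers had a median of 0.16 but a mean of −0.11, camera pointed down, and the list was not called (limma camera adjusted p = 0.44).

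In all, limma called 197 genes at 2 hours, 139 up and 58 down, of 775 with an unadjusted p under 0.05. Changes of at least 2-fold numbered 108 of these. The values of 814 genes (23.4%) did not overlap between the time points, where chance gives 10%. Leaving out 1 array moved the count by over 1.5 times in 5 cases, to 316 without 0 hours replicate 2, 116 without 0 hours replicate 3, 101 without 2 hours replicate 1, 107 without 2 hours replicate 2 and 72 without 2 hours replicate 3. It was 108 with the Gapdh ratio and 145 with the muscle marker mean as a covariate, both chosen after seeing the data. Camera called 11 of 28 gene lists, 7 up and 4 down, and none with an estimated correlation. Fry, which does not compare a list with other genes, called 2, heat shock (fry adjusted p = 0.0041) and oxidative stress genes (0.0042). Camera calls at 2 hours were lost for chemokines (adjusted p = 0.11), basal keratinocyte markers (0.14) and ribosomal proteins (0.072) without 0 hours replicate 1, for chemokines (0.38), hair follicle (0.076) and oxidative stress genes (0.26) without 0 hours replicate 2, and for matrix (0.072) and ribosomal proteins (0.067) without 0 hours replicate 3. They were also lost for chemokines (0.20) and basal keratinocyte markers (0.12) without 2 hours replicate 1, and for oxidative stress genes (0.13) without 2 hours replicate 2.

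**Figure D2:**
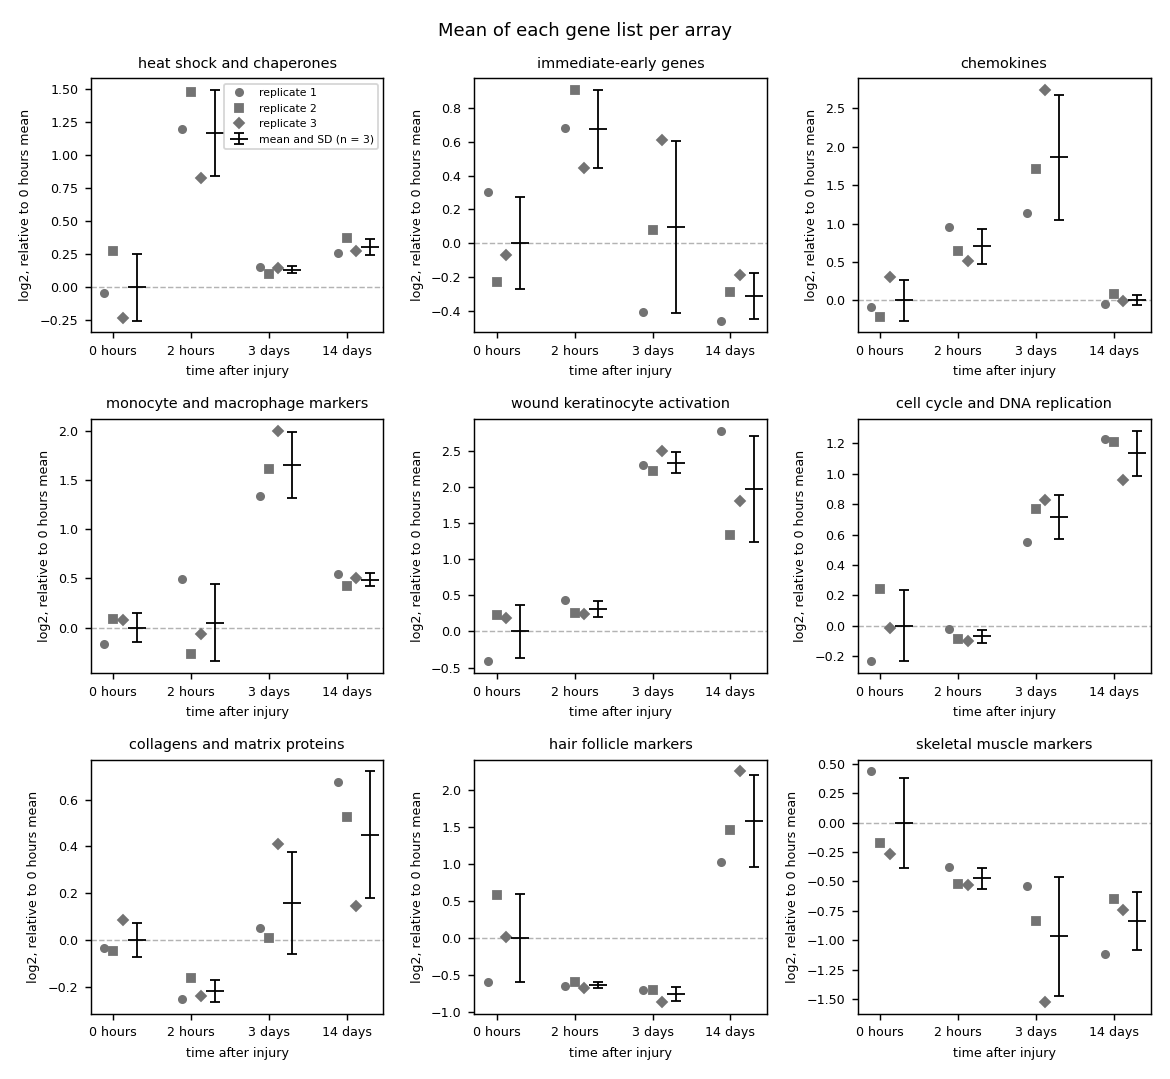
Mean log2 signal of 9 gene lists on each of the 12 arrays, relative to the 0 hours mean (dashed line), by time after injury; symbols mark replicates, and bars the mean and SD of 3 arrays. Heat shock genes stood highest at 2 hours, macrophage markers at 3 days and hair follicle markers at 14 days.

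The comparison of 3 days with 0 hours asks what the wound tissue held after some days. Markers of monocytes and macrophages rose nearly throughout: 23 of 24 tested rose, none fell and 1, Spi1, was not called, with a median log2 change of 1.59. All 24 passed adjusted over the list alone, and the list call was lost with an estimated correlation (adjusted p = 0.17 with an estimated correlation). The leukocyte surface protein Cd53 rose 7.16-fold (2.84 ± 0.25, limma adjusted p = 1.2e-05), the inhibitory Fc receptor Fcgr2b 4.61-fold (2.20 ± 0.25), the chemokine receptor Ccr2 by 1.89 ± 0.23 and the Fc receptor Fcgr1 by 1.89 ± 0.27. The Gapdh log2 ratio fell from 1.99 to 0.52 and the muscle marker mean from 12.60 to 11.64 between these time points.

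Chemokines and cytokines rose with them. Of 11 chemokines 8 rose, or 10 adjusted over the list alone, with a median of 1.99 (adjusted p = 0.17 with an estimated correlation). The neutrophil attractants Cxcl5 and Cxcl2 were at the floor on all 3 arrays at 0 hours and rose by at least 3.46 and at least 3.13 on the log2 scale. Without 3 days replicate 3 the changes were 2.67 and 2.43, and that of Cxcl2 was 3.82 without 3 days replicate 1. Ccl8 rose by 2.72 ± 0.36 and Ccl9 by 2.17 ± 0.30. Of 13 cytokines and receptors 6 rose, or 8 up and 1 down adjusted over the list alone, with a median of 0.72 (adjusted p = 0.17 with an estimated correlation). They included Il1b, at the floor at 0 hours and at least 8.78-fold higher (log2 change 3.84 without 3 days replicate 1 and 2.38 without 3 days replicate 3), Il4ra (2.37 ± 0.36), Tnfrsf1b (1.21 ± 0.21) and Csf3 (1.76 ± 0.35, and −0.14 with the Gapdh ratio as a covariate). Of 11 acute phase and antimicrobial genes 5 rose, or 7 adjusted over the list alone, with a median of 1.23 (adjusted p = 0.17 with an estimated correlation). Saa3, serum amyloid A3, rose at least 44.8-fold (5.48 ± 0.65, and 6.35 without 3 days replicate 1), with 2 of 3 arrays at the floor at 0 hours. S100a8 rose at least 30.6-fold (4.94 ± 0.76), with 1 array at the floor, and its partner S100a9, at the floor at 0 hours, rose at least 17.8-fold, beside Slpi (1.83 ± 0.33, other probe set 3.01) and Lyz2 (1.45 ± 0.28).

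Of 13 complement and coagulation genes 5 rose, or 6 adjusted over the list alone, with a median of 0.44 (adjusted p = 0.17 with an estimated correlation). They were C1qb (1.87 ± 0.27), Cfp (1.82 ± 0.27), C3ar1 (1.38 ± 0.22), C1qc (1.46 ± 0.29) and C1qa (2.03 ± 0.41). Ifi204 (1.18 ± 0.21) and Isg15 (1.19 ± 0.32) rose among 12 interferon response genes, or 3 adjusted over the list alone, with a median of 0.57 (adjusted p = 0.36 with an estimated correlation), and the call of Isg15 was lost without 3 days replicate 3 (limma adjusted p = 0.080). Of 7 genes of MHC class II presentation only Ctss, a lysosomal protease, rose (2.01 ± 0.30), or 1 adjusted over the list alone, with a median of 0.51 (adjusted p = 0.52 with an estimated correlation). The lists overlap: C1qa, C1qb, C1qc, Ctss and Lyz2 are also macrophage markers here, and Ctss is in the matrix protease list too. Calls of these lists are therefore not separate in every comparison.

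Genes of the wound keratinocyte list rose strongly at 3 days. Of 14 wound keratinocyte genes 11 rose, or 12 adjusted over the list alone, with a median of 2.07 (adjusted p = 0.17 with an estimated correlation). Krt16, a keratin of activated epidermis, rose at least 33.7-fold (5.07 ± 0.54), with 2 of 3 arrays at the floor at 0 hours, Krt6b rose 28.8-fold (4.85 ± 0.56), the gap junction protein Gjb2 11.9-fold (3.57 ± 0.35), Sprr1a 6.06-fold (2.60 ± 0.32) and Sprr2b at least 22.1-fold (4.47 ± 0.68), with 1 array at the floor. Without 0 hours replicate 1 the change of Sprr2b was 3.53, and without 0 hours replicate 2 it was 5.19. Krt6b and Sprr2b belong to families of near-identical members, so their identity is uncertain. The protease Klk6 was at the floor at 0 hours and rose at least 13.4-fold. Of 12 basal keratinocyte markers, Lama3 (1.10 ± 0.26), Jup (1.01 ± 0.28) and Sfn (0.86 ± 0.27) rose, or 4 adjusted over the list alone, and the list was not called (limma camera adjusted p = 0.16). Without 3 days replicate 3 these calls were lost, with limma adjusted p of 0.053, 0.13 and 0.21.

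Of 17 cell cycle and DNA replication genes 5 rose at 3 days, or 9 adjusted over the list alone, with a median of 0.58 (adjusted p = 0.17 with an estimated correlation). They were the replication licensing genes Mcm5 (1.83 ± 0.22) and Mcm3 (1.22 ± 0.19), Cdk1 (1.34 ± 0.18), Tk1 (1.14 ± 0.27) and Rrm2 (0.66 ± 0.21). Without 3 days replicate 3 the calls of Tk1 and Rrm2 were lost, with limma adjusted p of 0.058 and 0.21. Of 19 matrix proteases and inhibitors 9 rose and 1, Ctsk, fell, or 10 and 1 adjusted over the list alone, with a median of 0.79 (adjusted p = 0.25 with an estimated correlation). The protease inhibitor Timp1 rose 8.75-fold (3.13 ± 0.47, and 3.73 without 3 days replicate 1), beside Adam8 (2.47 ± 0.30), Ctss and Ctsl (1.28 ± 0.20). The matrix list was not called (limma camera adjusted p = 0.72), with 3 of 36 up and 3 down, or 4 and 3 adjusted over the list alone. Tnc, a matrix protein of healing wounds, was at the floor at 0 hours and rose at least 10.4-fold, and Col18a1 (0.87 ± 0.20) and Fbln1 (0.79 ± 0.20) rose. Col1a2 (fell by 1.27 ± 0.19), Sparc (fell by 1.15 ± 0.19) and Col1a1 (fell by 0.95 ± 0.18) fell, with other probe sets of Col1a2 and Col1a1 at −0.44 and −2.23. Without 3 days replicate 3 the calls of Col18a1, Fbln1 and Ctsk were lost, with limma adjusted p of 0.055, 0.078 and 0.051. Rrm2, C1qa, Lyz2, Ctsk, Col18a1, Fbln1 and Spi1 were named after their values were seen.

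Skeletal muscle transcripts fell at 3 days, beside the lower muscle marker mean and Gapdh ratio. Of 34 markers 19 fell and none rose, or 27 fell adjusted over the list alone, with a median of −1.14 (adjusted p = 0.25 with an estimated correlation). Myoz1, a protein of the Z-disc, fell by 1.76 ± 0.29, Cox8b fell by 1.47 ± 0.31, Mylpf fell by 1.11 ± 0.23 and Myl1 fell by 1.26 ± 0.27. Tnnc2 fell by 1.60 ± 0.35, Ryr1 fell by 1.59 ± 0.35, and outside the list the sarcomere gene Myom1 fell by 1.75 ± 0.39, Ank1 fell by 1.67 ± 0.24 and Sh3bgr fell by 1.67 ± 0.33. The call of Myom1 was lost without 3 days replicate 3 (limma adjusted p = 0.051). Of 29 genes of oxidative phosphorylation and the citric acid cycle 3 fell, or none adjusted over the list alone, with a median of −0.59 (adjusted p = 0.43 with an estimated correlation). They were Idh2 (fell by 0.83 ± 0.24), Ndufv1 (fell by 0.81 ± 0.25) and Sdhb (fell by 0.93 ± 0.29). All 3 calls were lost without 3 days replicate 3, with limma adjusted p of 0.15, 0.19 and 0.21. With the muscle marker mean as a covariate the sign turned for Sdhb, to a rise of 0.15. Of 15 hair follicle markers Krt71 fell at least 4.05-fold, being at the floor at 3 days (log2 change −2.79 without 0 hours replicate 1), and S100a3 fell by 1.62 ± 0.41, or 3 adjusted over the list alone, with a median of −0.59 (adjusted p = 0.42 with an estimated correlation). The other probe set of S100a3 gave −0.01, and its call was lost without 3 days replicate 3 (limma adjusted p = 0.071). At 3 days the changes of Fcgr1, Csf3, C3ar1, Isg15, Cdk1, Tk1, Rrm2, Adam8 and S100a3 are also lower bounds in size, because 1 or 2 of the 3 arrays of the lower group were at the floor.

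In all, limma called 462 genes at 3 days, 309 up and 153 down, of 1037 with an unadjusted p under 0.05, and 257 of them changed at least 2-fold. The split was 284 up and 209 down with quantile normalization, and 272 up and 205 down without 0 hours replicate 3. Without 3 days replicate 3 it was 145 up and 33 down. The values of 994 genes (28.6%) did not overlap, where chance gives 10%. The count moved to 297 without 3 days replicate 2 and to 178 without 3 days replicate 3, and it fell to 4 with the Gapdh ratio as a covariate and to 5 with the muscle marker mean as a covariate, both chosen after seeing the data. Camera called 13 of 28 lists, 10 up and 3 down, none of them with an estimated correlation. Fry called 13 too, but not the same ones. It did not call MHC class II (fry adjusted p = 0.10), oxidative phosphorylation (0.10) or hair follicle genes (0.13). Instead it called oxidative stress genes (0.021), myofibroblast (0.017) and nerve markers (0.029), which camera did not call. The camera call of MHC class II genes was lost without 0 hours replicate 1 (adjusted p = 0.081), 0 hours replicate 2 (0.12) or 3 days replicate 2 (0.080), and that of interferon response genes without 3 days replicate 1 (0.056).

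**Figure D3:**
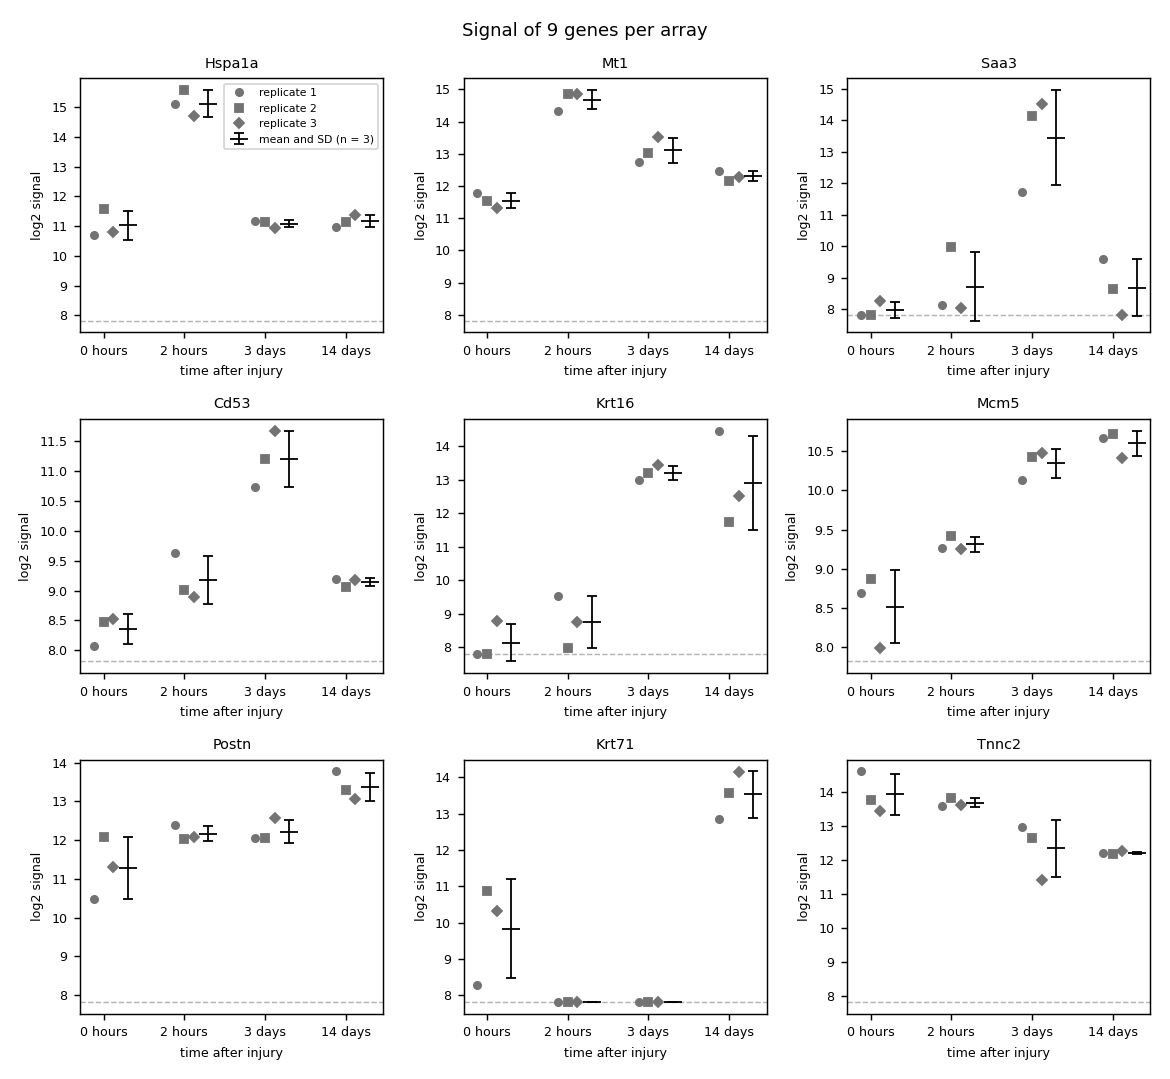
Log2 signal of 9 genes on each of the 12 arrays by time after injury; symbols mark replicates, bars the mean and SD of 3 arrays, and the dashed line the floor of 225.375 signal units. Hspa1a changed by 4.09 at 2 hours, Saa3 by at least 5.48 at 3 days and Krt71 by 3.69 at 14 days, each on the log2 scale against 0 hours.

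The comparison of 14 days with 0 hours asks what differed late after the injury. Genes of the cell cycle, of wound keratinocytes and of the hair follicle were higher, and muscle genes were lower. Of 17 cell cycle and DNA replication genes 14 rose and none fell, or 16 adjusted over the list alone, with a median of 1.04 (adjusted p = 0.18 with an estimated correlation). Mcm5 rose 4.25-fold (2.09 ± 0.22, limma adjusted p = 9.8e-05), Cdk1 by 1.68 ± 0.18, the proliferation marker Mki67 by 1.51 ± 0.22 and Stmn1, a microtubule regulator, by 2.18 ± 0.35. The Gapdh log2 ratio was 0.21 against 1.99 at 0 hours, and the muscle marker mean 11.77 against 12.60.

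Of 14 wound keratinocyte genes 9 rose at 14 days, or 11 adjusted over the list alone, with a median of 1.46 (adjusted p = 0.43 with an estimated correlation). Krt16 was at least 27.3-fold higher (4.77 ± 0.54), Sprr2b at least 20.4-fold (4.35 ± 0.68), each with arrays at the floor at 0 hours, Krt6b 16.3-fold (4.03 ± 0.56), Gjb2 10.6-fold (3.41 ± 0.35) and Sprr1a 6.05-fold (2.60 ± 0.32), with the identity of Krt6b and Sprr2b uncertain as before. Krt16 changed by 3.99 and Krt6b by 3.15 without 14 days replicate 1, and by 5.36 and 4.75 without 14 days replicate 2. Sprr2b changed by 3.41 without 0 hours replicate 1 and by 5.07 without 0 hours replicate 2. Klk6, at the floor at 0 hours, rose by at least 3.32. Of 12 genes of epidermal differentiation and the barrier 4 rose, or 4 adjusted over the list alone, with a median of 0.34 (adjusted p = 0.58 with an estimated correlation). They were Flg, the barrier protein filaggrin, 7.07-fold higher (2.82 ± 0.24), Casp14 (2.80 ± 0.22), the suprabasal keratin Krt1 (2.19 ± 0.25) and the desmosomal cadherin Dsc1 (1.12 ± 0.26). The call of Dsc1 was lost without 14 days replicate 1 (limma adjusted p = 0.079). Of 15 hair follicle markers 9 rose, or 12 adjusted over the list alone, with a median of 1.34 (adjusted p = 0.43 with an estimated correlation). The inner root sheath keratins Krt71 and Krt25 were 12.9-fold (3.69 ± 0.48) and at least 12.6-fold (3.65 ± 0.48) higher, with changes of 2.92 for Krt71 without 0 hours replicate 1 and 4.39 for Krt25 without 0 hours replicate 2. The hedgehog receptor Ptch1 rose by 1.13 ± 0.20 and the hair keratin Krt35 by 1.80 ± 0.33.

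Of 36 collagens and matrix proteins 12 rose and 1, Sparc, fell at 14 days, or 15 and 3 adjusted over the list alone, with a median of 0.28 (adjusted p = 0.66 with an estimated correlation). The camera call was lost without 0 hours replicate 2 (adjusted p = 0.17) and without 14 days replicate 1 (adjusted p = 0.091). Thbs2 rose by 1.87 ± 0.28, the matricellular protein Postn by 2.09 ± 0.33, Col6a3 by 1.31 ± 0.22 and Tnc, at the floor at 0 hours, at least 5.65-fold (log2 change 1.89 without 14 days replicate 1). Of 19 matrix proteases and inhibitors, 5 rose and 1 fell, or 7 and 2 adjusted over the list alone, with a median of 0.36 (adjusted p = 0.66 with an estimated correlation). Mmp11 (1.47 ± 0.20), Timp2 (1.82 ± 0.29), Mmp9 (1.67 ± 0.33), Ctss (1.13 ± 0.30) and Adam8 rose, and Mmp3 fell by 1.36 ± 0.29. The call of Ctss was lost without 0 hours replicate 1 (limma adjusted p = 0.12). Of 24 macrophage markers 2, Lgals3 (0.76 ± 0.20) and Ctss, rose, or 4 adjusted over the list alone, with a median of 0.50 (adjusted p = 0.66 with an estimated correlation), and the call of Lgals3 was lost without 0 hours replicate 1 (limma adjusted p = 0.11). With the Gapdh ratio as a covariate the sign turned for the medians of macrophage markers (−0.40) and matrix proteases (−0.13) and for Adam8 (−0.38). Of 17 ribosomal protein genes Rpl13a (0.82 ± 0.20) and Rpl22 (0.90 ± 0.25) rose, or 5 adjusted over the list alone, with a median of 0.34 (adjusted p = 0.66 with an estimated correlation), and both were lost without 0 hours replicate 1, with limma adjusted p of 0.082 and 0.098. Without 14 days replicate 3 the calls of Sparc and Adam8 were lost, with limma adjusted p of 0.11 and 0.074. Sparc and Adam8 were named after their values were seen.

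Of 34 muscle markers 18 fell at 14 days and 1, Tpm1, rose, or 21 and 1 adjusted over the list alone, with a median of −1.07 (adjusted p = 0.56 with an estimated correlation). Tnnc2 fell by 1.73 ± 0.35, Cox8b fell by 1.46 ± 0.31, Mylpf fell by 1.03 ± 0.23, Myl1 fell by 1.16 ± 0.27 and Actn3 fell by 1.65 ± 0.38, whereas Tpm1, also made outside skeletal muscle, rose by 0.76 ± 0.21. Without 14 days replicate 1 the calls of Cox8b, Mylpf, Myl1, Actn3 and Tpm1 were lost, with limma adjusted p of 0.052, 0.052, 0.065, 0.081 and 0.14. Of 29 genes of oxidative phosphorylation and the citric acid cycle 0 were called by limma, and 0 adjusted over the list alone, with 16 down at an unadjusted p under 0.05, while the list median was −0.50 and camera called it down (adjusted p = 0.66 with an estimated correlation). Of 19 genes of fatty acid and sterol synthesis 5 fell, or 5 adjusted over the list alone, with a median of −0.07, and the list was not called (limma camera adjusted p = 0.083). They were Thrsp (fell by 2.53 ± 0.60, and by 1.82 without 0 hours replicate 1), the fatty acid synthase Fasn (fell by 2.39 ± 0.47), Me1 (fell by 1.34 ± 0.34), Acly (fell by 1.02 ± 0.21) and Scd1. Without 14 days replicate 1 the calls of Thrsp, Me1 and Scd1 were lost, with limma adjusted p of 0.063, 0.081 and 0.089. Of 18 adipocyte markers 1, Agt, fell by 1.41 ± 0.36, or 1 adjusted over the list alone, with a median of −0.63 (adjusted p = 0.66 with an estimated correlation), and its call was lost without 0 hours replicate 1 (limma adjusted p = 0.090). The immediate-early gene Fos had the largest fall (fell by 3.45 ± 0.58), with −2.86 without 0 hours replicate 1 and −4.08 without 0 hours replicate 2. Cdo1 (fell by 1.71 ± 0.47), Pcx (fell by 1.60 ± 0.48) and Phkg1 (fell by 1.55 ± 0.26) also fell, with the calls of Cdo1 and Pcx lost without 0 hours replicate 1 (limma adjusted p of 0.13 and 0.17, with a log2 change of −0.98 for Pcx). At 14 days the changes of Cdk1, Mki67, Dsc1, Ptch1, Timp2, Mmp9, Adam8, Agt, Pcx and Phkg1 are also lower bounds in size, because 1 or 2 of the 3 arrays of the lower group were at the floor. Scd1 was named after its values were seen.

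In all, limma called 353 genes at 14 days, 240 up and 113 down (68.0% up), of 975 with an unadjusted p under 0.05, and 196 of them changed at least 2-fold. With median scaling the split was 204 up and 163 down (55.6% up). Without 0 hours replicate 3 it was 193 up and 164 down, and without 14 days replicate 1 it was 101 up and 18 down. The values of 1013 genes (29.1%) did not overlap, where chance gives 10%. The count moved to 157 without 0 hours replicate 1, 119 without 14 days replicate 1, 211 without 14 days replicate 2 and 233 without 14 days replicate 3, and it was 2 with the Gapdh ratio and 15 with the muscle marker mean as a covariate, both chosen after seeing the data. Camera called 11 of 28 lists, 8 up and 3 down, none with an estimated correlation. Fry called 4, cell cycle (fry adjusted p = 0.00043), wound keratinocyte (0.0054), epidermal differentiation (0.0054) and hair follicle genes (0.012). The camera call of adipocyte markers was lost without 0 hours replicate 1 (adjusted p = 0.25, with a list median of −0.19). That of matrix proteases was lost without 14 days replicate 1 (camera adjusted p = 0.11).

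Between 2 hours and 3 days heat shock genes fell, and macrophage and wound keratinocyte genes rose. Hspa1a fell by 4.04 ± 0.26, Hspa1b fell by 3.27 ± 0.31, Pdk4, a regulator of pyruvate use, fell by 3.16 ± 0.34 and Hsph1 fell by 2.53 ± 0.32. Krt6b rose 36.3-fold (5.18 ± 0.56), Saa3 26.7-fold (4.74 ± 0.65), Gjb2, with 1 array at the floor at 2 hours, at least 23.3-fold (4.55 ± 0.35) and Krt16 21.9-fold (4.45 ± 0.54). Saa3 changed by 5.36 without 2 hours replicate 2 and by 5.60 without 3 days replicate 1. Of 20 heat shock genes 10 fell and none rose, or 13 fell and 1 rose adjusted over the list alone, with a median of −0.72 (adjusted p = 0.16 with an estimated correlation). Of 24 macrophage markers 21 rose, or 23 adjusted over the list alone, with a median of 1.67 (adjusted p = 0.13 with an estimated correlation). Of 17 cell cycle genes 9 rose, or 12 adjusted over the list alone, with a median of 0.83 (adjusted p = 0.13 with an estimated correlation). Of 14 wound keratinocyte genes 9 rose and 1, S100a10, fell, or 11 and 1 adjusted over the list alone, with a median of 1.48 (adjusted p = 0.16 with an estimated correlation). Of 19 matrix proteases and inhibitors 10 rose and 1, Timp3, fell, or 12 and 1 adjusted over the list alone, with a median of 0.85 (adjusted p = 0.13 with an estimated correlation). In all, limma called 327 genes, 212 up and 115 down, and camera 15 lists, none with an estimated correlation. The gene count moved to 156 without 2 hours replicate 2, 141 without 2 hours replicate 3, 134 without 3 days replicate 2 and 112 without 3 days replicate 3. It was 935 (474 up, 461 down) with array weights, and 16 with the Gapdh ratio and 98 with the muscle marker mean as a covariate, both covariates chosen after seeing the data. Without 3 days replicate 3 the calls of S100a10 and Timp3 were lost, with limma adjusted p of 0.16 and 0.12. S100a10 and Timp3 were named after their values were seen.

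Between 3 days and 14 days the inflammatory transcripts fell and hair follicle transcripts rose, and 6 lists were called by limma camera with an estimated correlation too. Of 15 hair follicle markers 12 rose, or 13 adjusted over the list alone, with a median of 1.87 (adjusted p = 0.029 with an estimated correlation). Krt71, Krt25 and Krt27 were at the floor at 3 days and rose at least 52.3-fold, at least 25.1-fold and at least 17.8-fold, and S100a3 rose by 3.45 ± 0.41. Of 24 macrophage markers 12 fell, or 23 adjusted over the list alone, with a median of −1.07 (adjusted p = 0.033 with an estimated correlation). Of 11 chemokines 7 fell, or 10 adjusted over the list alone, with a median of −2.10 (adjusted p = 0.033 with an estimated correlation), among them Cxcl5 and Cxcl2, which reached the floor at 14 days with log2 changes of −3.46 and −3.13 as bounds (−2.67 and −2.43 without 3 days replicate 3, and −3.82 for Cxcl2 without 3 days replicate 1). Of 13 cytokines and receptors Il1b (fell by 3.07 ± 0.48, with −3.78 without 3 days replicate 1 and −2.32 without 3 days replicate 3), Osmr, Csf1 and Il4ra fell, or 8 adjusted over the list alone (adjusted p = 0.033 with an estimated correlation). Of 11 acute phase genes Saa3 (fell by 4.77 ± 0.65, and by 5.63 without 3 days replicate 1) and S100a9 (fell by 2.58 ± 0.66, and by 3.41 without 14 days replicate 1) fell, or 9 adjusted over the list alone, and of 13 complement and coagulation genes C1qb, C3ar1 and Cfp fell, or 5 adjusted over the list alone (adjusted p = 0.029 with an estimated correlation for each list). Of 12 epidermal differentiation genes Krt1, Flg, Casp14 and Dsc1 rose, or 5 adjusted over the list alone (adjusted p = 0.085 with an estimated correlation). In all, limma called 118 genes, 45 up and 73 down, and camera 19 lists, 6 up and 13 down. The gene count moved to 69 without 3 days replicate 2, 64 without 3 days replicate 3, 59 without 14 days replicate 2 and 76 without 14 days replicate 3. It was 364 with array weights, and 123 with the Gapdh ratio and 132 with the muscle marker mean as a covariate, both covariates chosen after seeing the data. The changes of S100a3, Il1b and Saa3 are lower bounds in size, because 1 or 2 of the 3 arrays of the lower group were at the floor. Without 3 days replicate 3 the calls of Osmr, Csf1, S100a9, C1qb, C3ar1 and Dsc1 were lost, with limma adjusted p of 0.11, 0.090, 0.21, 0.075, 0.16 and 0.13. Osmr, Csf1, Il4ra, S100a9, C1qb, C3ar1, Cfp, Krt1, Flg, Casp14 and Dsc1 were named after their values were seen.

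The comparisons with 0 hours shared calls. Of the genes up at 3 days and at 14 days 114 were shared and of those down 70, where independent lists would share 21.3 and 4.97. Between 2 hours and 3 days 58 up and 20 down were shared, against 12.4 and 2.55, and between 2 hours and 14 days 33 up and 11 down, against 9.59 and 1.88. In 50 simulations of unchanged groups against the same controls 0 calls were shared on average, but groups without an effect give few calls, so this value is no reference for sharing among many calls. Part of the excess may come from the shared 0 hours arrays, because 3 arrays cannot be split into groups of at least 2.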

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

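Among the tests here, the melanocyte test and the covariates for the Gapdh 3′ to 5′ ratio and the muscle marker mean were chosen only after the result was seen. A difference between time points marked 4 genes for a closer look: each was called against 0 hours in opposite directions at 2 time points, so a limma test of the difference between them restates that choice and its p adds no support. Cebpd rose by 1.78 at 2 hours and fell by 1.00 at 14 days, a difference of −2.78. Mfap2 fell by 0.91 at 2 hours and rose by 1.03 at 14 days, a difference of 1.94. Krt71 fell at least 4.05-fold at 2 hours and at 3 days and rose by 3.69 at 14 days, a difference of at least 5.71 from each. S100a3, with 1 array at the floor at 2 hours and 2 at 3 days, differed by at least 3.35 between 2 hours and 14 days and by at least 3.45 between 3 days and 14 days, while its other probe set was at −0.01 against 0 hours at 2 hours and at 3 days. Without 14 days replicate 1 the 14 days calls of Cebpd and Mfap2 were lost, with limma adjusted p of 0.11 and 0.055.

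Outside the gene tests, 401 probe sets that name no gene or several were tested. Of these, limma called 17 at 2 hours (11 up, 6 down), 35 at 3 days (27 up, 8 down) and 37 at 14 days (22 up, 15 down). Among the 3477 named genes it called 197, 462 and 353. The share called was thus lower among these probe sets at each time, so they give no separate signal.

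The fall of muscle and oxidative phosphorylation genes against 0 hours is open to technical explanations. Less skeletal muscle in the excised tissue was tested for the oxidative phosphorylation fall. With the muscle marker mean as a covariate the list median went from −0.59 to 0.12 at 3 days. At 14 days it went from −0.50 to 0.099, and the errors of the list mean were 0.23 and 0.21. The muscle mean also moves with time, and with it the changes of all called genes shrank. Their median absolute change went from 1.05 to 0.71 at 3 days and from 1.04 to 0.76 at 14 days. This fit therefore cannot tell less muscle apart from the time of excision. For the muscle list, the spread of changes among bright members was 1.43 (3 days) and 1.64 (14 days) times their standard error. This was under the bound of 2 set for a shift of the whole tissue share. Members that all fell alike would spread by about their standard error or less. The bound therefore cannot decide whether the whole list shifted alike. Both values lay above the spread of an equal fall, which leans toward unequal falls, but their own error was not computed. RNA quality as read by the Gapdh ratio cannot be told apart from the time of excision for either list, because that ratio moves with time and the covariate widens the errors between arrays. With it the oxidative phosphorylation medians were −0.56 and −0.51 with errors of the list mean of 0.53 and 0.62, and the muscle medians were −0.64 and −0.51 with errors of 0.58 and 0.67.

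The rise of hair follicle genes from 3 to 14 days had a median of 1.87. Loss of another tissue would raise the markers of all remaining cell types alike, but the highest median of fibroblast, endothelial, adipocyte and basal keratinocyte markers was 0.11. Growing follicles may be the source as a hypothesis: growing follicles also hold pigment cells, and the melanocyte list, with 3 genes, had a median of 1.57. Dct and Pmel rose by 1.57 and 1.88 and Sox10 was not called (0.35), so the pigment genes rather than the number of pigment cells may have changed. A difference in the hair cycle between the animals, from their age or from shaving, was not tested.

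With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many called genes. The real and highest other counts were 197 and 1 at 2 hours, 462 and 0 at 3 days, 353 and 1 at 14 days, 327 and 1 for 3 days against 2 hours, and 118 and 1 for 14 days against 3 days. The gene lists called by camera at its preset correlation are less secure: the real and highest other counts were 11 and 8 at 2 hours, 13 and 14 at 3 days, where 2 splits gave as many, and 11 and 10 at 14 days. For the F-test over the 4 time points, 100 splits of the 12 arrays were used. Only 1, the real split, gave 736 genes, and the highest other count was 70. A random assignment of these arrays to groups is thus unlikely to give that count. The splits cannot exclude differences between animals or RNA preparations that go with the time point. The labels do not say whether the replicates came from separate animals.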

How the results depend on the processing

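The Gapdh and muscle covariates and the test without muscle and oxidative phosphorylation genes were chosen after seeing the data. Counts of called genes stayed within 1.5 times of 197, 462, 353, 327 and 118 (2 hours, 3 days and 14 days against 0 hours, 3 days against 2 hours, 14 days against 3 days) under quantile normalization, median scaling, both floors, the filter at the 75th percentile, the highest-variance probe set, trended and robust variance, and the replicate block (148, 412, 317, 256 and 88). Without muscle and oxidative phosphorylation genes they were 200, 440, 332, 326 and 118. Without a filter they fell to 294 at 3 days, 174 for 3 days against 2 hours and 63 for 14 days against 3 days, with 5599 genes tested. Array weights, from 0.35 for 0 hours replicate 3 to 4.08 for 3 days replicate 2, moved them to 119 at 2 hours, 935 for 3 days against 2 hours (474 up, 461 down) and 364 for 14 days against 3 days; the cause was not tested. A log2 change of at least 1 left 108, 257, 196 and 188 in the first 4 comparisons. Fits of only the 2 time points, with fewer arrays, left 63, 216 and 153 against 0 hours.

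With the Gapdh ratio as a covariate the counts were 108, 4, 2 and 16 in the first 4 comparisons. With the muscle marker mean they were 5 at 3 days, 15 at 14 days and 98 for 3 days against 2 hours. Among the genes called at 3 days the median absolute log2 change and standard error went from 1.05 and 0.24 to 0.73 and 0.48 with the Gapdh ratio and to 0.71 and 0.34 with the muscle mean. At 14 days they went from 1.04 and 0.24 to 0.74 and 0.56, and to 0.76 and 0.31. The calls ended because the change shrank and the error grew, since both covariates move with time. The same sign was held by 96.5% and 97.0% at 3 days and by 96.3% and 99.4% at 14 days. Signs reversed with the Gapdh ratio for Csf3 at 3 days (−0.14) and, at 14 days, for Hsp90aa1 (−0.17), Tgfb1 (−0.55), Slc2a1 (−0.0998), Adam8 (−0.38), matrix proteases (−0.13) and macrophage markers (−0.40), and with the muscle mean for Sdhb at 3 days (0.15); the cause was not tested.

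Camera with an estimated correlation called 0 lists at 2 hours, 0 at 3 days and 0 at 14 days, against 11, 13 and 11, with lowest adjusted p of 0.486, 0.165 and 0.180. Fry called 2 at 2 hours and 4 at 14 days, and the Gapdh covariate left 7 at 2 hours. Leaving out 1 array gave 8 to 12, 12 to 14 and 10 to 13 lists. It gave 72 to 316 genes at 2 hours, 178 to 558 at 3 days, 119 to 486 at 14 days, 112 to 409 for 3 days against 2 hours and 59 to 127 for 14 days against 3 days. Of 247 called results of named genes, 99 were lost without at least 1 array and 148 were kept without each in turn.

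Signal near background limits the dim genes: values at the floor give only bounds.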

Other observations

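Both tests of the glucocorticoid hypothesis, with the hypothesis and its gene list, were chosen only after the result was seen. Zbtb16, Pdk4 and Cebpd, genes known to respond to glucocorticoids, were higher at 2 hours by 2.33, 2.09 and 1.78. A glucocorticoid response at 2 hours may contribute. Among 25 other listed genes the median was 0.60, with 22 higher, 6 called up and 0 down. Mt1 and Mt2 were left out because their rise was already known. Camera gave p = 1.01e-06, and 0.0271 with an estimated correlation. Unlike those of the other lists, these p-values were not adjusted over lists. The heat shock list had an unadjusted camera p of 0.0239 with an estimated correlation, and 0.49 once adjusted. Of the 25 genes, 4 are also immediate-early genes. With the Gapdh ratio as a covariate the lowest of the 3 changes was 1.58. That log2 ratio overlapped between 0 hours (1.99 ± 0.29, SD) and 2 hours (1.54 ± 0.46). The median absolute change of all genes called at 2 hours hardly moved in that fit, from 1.06 to 1.04. The fit therefore cannot decide on RNA quality. The beta-actin 3′ to 5′ log2 ratio, 0.01 at 0 hours and 0.74 at 2 hours, was not fitted. Handling, anaesthesia or pain relief before excision was not tested.

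Some lists had fewer than 5 tested genes and no list test. Among 3 neutrophil genes at 3 days, S100a8 and S100a9 rose and Il1r2 was not called (−0.54). At 14 days S100a8 was not called (2.49, limma adjusted p = 0.052, with 1.52 without 14 days replicate 1 and 3.13 without 14 days replicate 2) and Il1r2 fell by 1.22. Of 4 mast cell genes, 4 were higher at 2 hours with a median of 0.76, and Cma1 rose (0.73), or 4 adjusted over the list alone, but without 2 hours replicate 1 the call of Cma1 was lost (limma adjusted p = 0.14). Of these genes, Cpa3 (1.11), Cma1 (0.76) and Hdc rose at 3 days, Hdc by at least 2.18 from the floor, and Tpsb2 (0.60) was not called. Hdc returned to the floor at 14 days. Of 4 sebaceous gland genes, Plin2 (1.14) and Fabp5 (1.08) rose at 3 days, and at 14 days Fabp5 rose by 1.30 and Scd1 fell by 1.07. Of 3 erythrocyte genes Hba-a1 fell by 1.04 at 14 days and Hbb-b2 (−0.53) was not called. Without 0 hours replicate 1 the calls of Cma1 and Fabp5 at 3 days and of Hba-a1 and Scd1 at 14 days were lost, with limma adjusted p of 0.079, 0.056, 0.094 and 0.14. Of B cell genes 1 was tested and not called in any comparison, and of T cell genes 0 were tested.

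Slfn4, a myeloid gene outside the lists, rose by at least 2.91 at 3 days and changed by −2.99 as a bound from 3 to 14 days, with 2 arrays at the floor at 0 hours and at 14 days, and was chosen after its values were seen, as were the genes of the small lists.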
